A study of Mus musculus with 32 samples.

How the data were processed

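RNA from the hearts of 32 individual C57BL/6 mice was hybridised to 1-colour Agilent mouse gene expression arrays with an array for each mouse, so each array is a separate animal. Per the labels, stressed mice were exposed to an aggressor mouse for 6 hours a day over 5 or 10 days (T5, T10) and then rested for 1, 10 or 42 days (R1, R10, R42), while controls stayed in mesh boxes without an aggressor. The 4 conditions (T5R1, T5R10, T10R1 and T10R42) each had their own 4 stressed and 4 control mice, which makes 8 groups. The 8 arrays of a condition shared a slide, so slide and condition are the same factor. On every slide the controls occupied the first 2 columns of arrays and the stressed mice the other two, so array column and stress are also the same factor, whereas both slide rows held both arms. The T10R1 slide was scanned on the first of 2 days, the others on the second.

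The deposited scanner files hold intensity values per spot: per the file headers, Agilent Feature Extraction 10.7.3.1 detrended and background-subtracted each spot and replaced spots not above background by a surrogate. The deposited scanner files also hold other values, namely flags of 0 or 1 per spot for being well above background, saturated or an outlier. The authors' value table holds log2 values. Its columns match the log2 mean spot signal without background subtraction (correlation of at least 0.99951, against at most 0.98324 with the log2 processed signal), quantile normalised within each slide. Sorted columns lay within 0.00534 of their slide's mean and up to 0.342 from the mean of all slides. The table is not centred by gene or turned into ratios, since its column medians were 5.854 for the T10R1 slide, 6.027 for T10R42, 6.259 for T5R10 and from 6.223 to 6.224 for T5R1. It was used only as an alternative.

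Of 62976 spots, 3671 were controls, and the other 59305 carried 55681 probes. Of these, 26413 probes were named by RefSeq accession from a gene table of assembly GRCm38.p6, 574 through the array's name of another probe, and 28694 kept the array's own name, which gave 36409 names, 19508 of them official symbols. Positions are those of the array design on mm9. Spots marked as outliers (5470) were left out, spots of a probe were averaged, and no probe value was saturated. A probe was kept if it was well above background on at least 3 of the 4 arrays of at least 1 group and missing on at most 4 arrays. That left 38824 probes, and of several probes of a gene (7323 genes) the brightest was used, so 27532 genes were tested, 15877 of them with an official symbol; 54 values were missing. The arrays had from 28792 to 40672 probes well above background and a 75th percentile signal from 237.2 to 498.9. Pairs of arrays of a group correlated at 0.9821 to 0.9943. Added spike-in RNA (7 probes with a mean log2 signal of at least 6) lay 3.30 to 4.89 log2 units above the 75th percentile. The scanner software marked 3 arrays for evaluation: T5R10 control replicate 4 and stressed replicates 1 and 2. Array number, at 4 mice per group, limits the precision, and no interval for counting error applies to arrays.

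The values analysed were log2 processed signal minus each array's 75th percentile. limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8) fitted a mean for each of the 8 groups over all 32 arrays, with 24 residual and 2.28 prior degrees of freedom. All tests were two-sided, and genes with a Benjamini-Hochberg adjusted p below 0.05 over the tested genes were called. Contrasts were stressed minus control in each condition, the mean of these 4, and the difference of stress effects between T5R10 and T5R1, T10R42 and T10R1, and T10R1 and T5R1. A gene well above background on none of the 4 arrays of a group is given as a lower bound of its fold against the level of background. The words rose and fell are used of genes called by limma, or of lists called by camera.

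Gene lists, groups, contrasts, tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, per contrast, the 10 called genes with an official symbol and the largest rise and the 10 with the largest fall (the 5 with the smallest p where none passed), up to 4 called members of each list (or the 2 with the smallest p), and Fkbp5, Per1, Nppa and Nppb throughout. For differences of stress effects it named the 5 with the smallest p in each direction. The text names a part of these, and some are not reported here.

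The 33 lists held 682 genes, 636 of them tested. They were glucocorticoid receptor targets, immediate early genes, acute inflammation, neutrophil, monocyte and macrophage, B cell, T and NK cell, thymocyte and erythroid markers, platelet genes, coagulation and fibrinolysis, collagen and extracellular matrix, matrix remodelling enzymes and inhibitors, fibroblast, endothelial, and smooth muscle and pericyte markers, cardiac contractile genes, cardiac stress and fetal genes, atrial, skeletal muscle, lung and adipocyte markers, fatty acid oxidation, oxidative phosphorylation, glycolysis, circadian clock, cell cycle, heat shock and unfolded protein response, interferon response, MHC class II and antigen presentation, NRF2 and oxidative stress, adrenergic, calcium handling and ion channel, and cholesterol and lipid synthesis genes. limma's camera tested them against the other genes with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data, which is stricter for lists whose genes move together between mice. limma's fry, which asks only whether a list's genes move on balance one way, was a further alternative. Adjustment was over the 33 lists of a contrast. In called lists of the 4 conditions, their mean and their differences, median, mean and camera direction had the same sign.

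Tested on simulated data with 200 changed genes among 27532, the T5R1 comparison recovered 34.3% of changes of 0.5 log2, 70.1% of 1 and 97.0% of 2, with 4 false calls. For T5R10 the shares were 40.3%, 77.6% and 93.9% with 12 false calls, for T10R1 46.3%, 68.7% and 92.4% with 5, and for T10R42 29.9%, 68.7% and 98.5% with 4. Camera called the 1 shifted list and 0 others. Such noise may be too mild: other splits of T5R10 arrays called up to 1264 genes. Alternatives were quantile normalisation, normexp background correction with an offset of 50, the authors' values, other probe filters, single probes, smaller fits, array weights, another variance prior, an adjusted p of 0.1, replicate blocks and leaving out each array. Row blocks, leaving out marked arrays, and list tests without each array were added after seeing the data. An exact permutation p for 4 mice against 4 is at least 0.0286, which is also the share of genes whose arms chance separates fully. It is printed for some lists only.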

Results

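Heart RNA was measured in 32 mice, 4 in each of 8 groups of stressed or control animals. Stress meant daily exposure to an aggressor mouse, a laboratory model of posttraumatic stress disorder, and the series varied the days of exposure (T) and the days of rest that followed (R). In total 27532 genes were tested. The questions were what stress does in each condition, what persists after rest, and whether longer exposure differs. Changes are stressed minus control on the log2 scale with their standard error (SE, n = 4 per arm). P values are two-sided and, except exact permutation and Fisher p, adjusted. List counts come with the count adjusted over the list alone.

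After 5 days of exposure and 1 day of rest (T5R1), stressed hearts had more RNA for dividing cells, for collagen matrix and for macrophage markers. The lists of mitochondrial energy metabolism were called lower, but not with an estimated correlation (adjusted p = 0.275 and 0.3). Birc5, an inhibitor of cell death needed for cell division, rose by 2.37 ± 0.20 (adjusted p = 9.14e-08), and Col3a1, which encodes the main chain of type III collagen, rose by 2.95 ± 0.32 (adjusted p = 1.2e-06). Serpina3n, an acute phase protease inhibitor, rose by 2.48 ± 0.25 (adjusted p = 4.96e-07). Cox4i1, a subunit of cytochrome c oxidase, had a change of -0.47 ± 0.07 (adjusted p = 6.43e-05), but did not pass under quantile normalisation or with the authors' values. In total 3778 genes passed, 1458 higher and 2320 lower, and 378 of the higher genes but 149 of the lower ones changed at least 2-fold. The probes lie, on mm9, on chromosome 11 from 117716978 to 117717037 for Birc5, chromosome 1 from 45405589 to 45405648 for Col3a1, chromosome 12 from 105651918 to 105651977 for Serpina3n and chromosome 8 from 123197924 to 123197983 for Cox4i1.

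**Figure D1:**
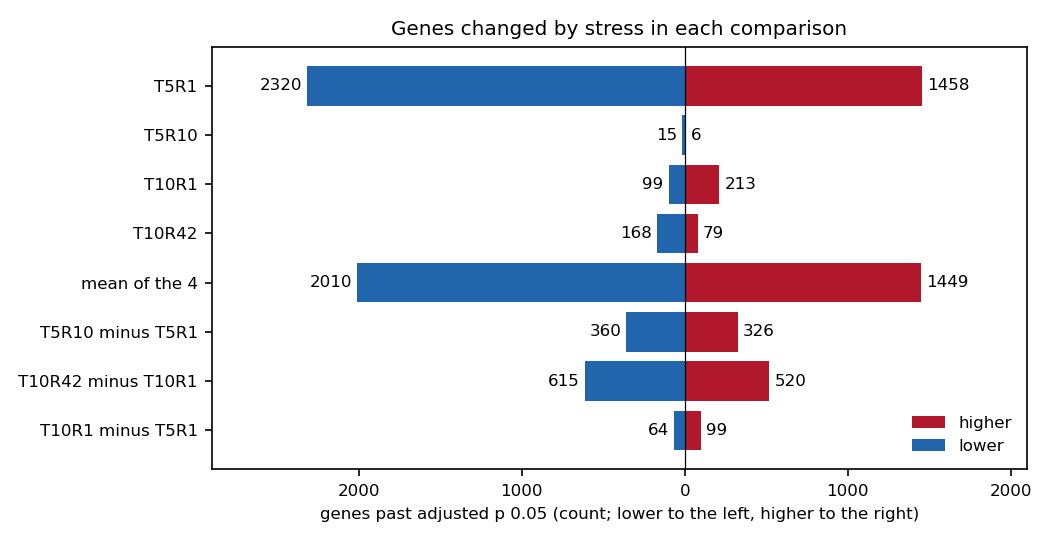
Number of genes past an adjusted p of 0.05 in each comparison, with higher genes drawn to the right and lower genes to the left of 0. T5R1 had 1458 higher and 2320 lower genes and T5R10 had 6 and 15.

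Among the lists, cell cycle genes had the highest median in T5R1. Of 31 genes 27 rose (27 adjusted over the list alone, where 1 more was lower), and the adjusted p was 1.16e-42, or 0.00749 with an estimated correlation. The median change was 1.80, or 1.60 with 4 genes at background in the controls set to their lower bounds. The mean of the list was higher by 1.33 to 1.85 in the 4 stressed hearts, against controls between -0.04 and 0.06 (exact permutation p = 0.0286, the smallest possible). Pbk, a mitotic kinase, was at least 3.24-fold higher, Ska1, which ties chromosomes to the spindle, at least 2.99-fold, and the spindle checkpoint kinase Bub1 at least 1.79-fold. Each was above background in 0 of 4 control hearts and in all 4 stressed hearts. Top2a, which untangles DNA in mitosis, rose by 2.73 ± 0.38 with 1 control array above background. Cdca3, which helps cells enter mitosis, rose by 3.20 ± 0.28 with 2 control arrays above background.

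Of 29 collagen and matrix genes 24 rose in T5R1 (24 adjusted over the list alone), with a median of 1.35. The adjusted p was 5.3e-40, or 0.00875 with an estimated correlation. Postn, a matrix protein of activated fibroblasts, rose by 3.02 ± 0.42, Col1a1, a chain of type I collagen, by 2.53 ± 0.30 and the collagen crosslinking enzyme Lox by 2.21 ± 0.39 (1 control array above background). Cthrc1, a secreted protein of remodelling tissue, was at least 10.1-fold higher, above background on 0 of 4 control arrays. Among matrix remodelling enzymes and inhibitors 9 of 21 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 5.46e-07, and 0.00875 with an estimated correlation). The metalloproteinase inhibitor Timp1 rose by 2.80 ± 0.32 and the procollagen peptidase Adamts2 by 1.36 ± 0.17. The inhibitor Timp4, abundant in heart, fell by 1.44 ± 0.35. Fibroblast markers rose in 9 of 17 and fell in 1 (12 and 2 adjusted over the list alone; adjusted p = 1.49e-12, and 0.0149 with an estimated correlation). The microfibril protein Mfap5 rose by 1.46 ± 0.20.

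Markers of some immune cells were higher in T5R1, and whether cells had come in or resident cells had changed was not tested. Macrophage markers rose in 12 of 20 (15 higher and 1 lower adjusted over the list alone; adjusted p = 3.64e-10, and 0.043 with an estimated correlation). The lysosomal protein Cd68 rose by 1.17 ± 0.20, the inhibitory receptor Lilrb4a by 1.18 ± 0.21 and the monocyte recruitment receptor Ccr2 by 1.5 ± 0.45. Acute inflammation genes rose in 6 of 24 (6 adjusted over the list alone; adjusted p = 1.17e-05, and adjusted p = 0.147 with an estimated correlation). One of them, the chemokine Ccl3, was at least 1.24-fold higher and above background on 0 of 4 control and 3 of 4 stressed arrays. Neutrophil markers rose in 4 of 11 (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0115, and adjusted p = 0.236 with an estimated correlation). The calcium-binding alarmin S100a8 rose by 2.08 ± 0.57 with 3 control arrays above background, its partner S100a9 by 1.99 ± 0.58 and Lcn2, which binds iron carriers, by 1.87 ± 0.22. Interferon response genes rose in 13 of 30 and fell in 1 (15 and 1 adjusted over the list alone; adjusted p = 9.08e-12, and adjusted p = 0.16 with an estimated correlation). The chemokine Cxcl10 rose by 1.75 ± 0.41 and the ubiquitin-like Isg15 by 1.14 ± 0.20. Coagulation genes rose in 7 of 23 and fell in 1 (7 and 3 adjusted over the list alone; adjusted p = 0.000147, and 0.0338 with an estimated correlation).

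Erythroid markers were also higher, unevenly between hearts. They rose in 5 of 14 (5 adjusted over the list alone; adjusted p = 0.00103, and adjusted p = 0.39 with an estimated correlation). Means of the erythroid markers were 0.28, 0.57, 1.78 and 0.47 in the stressed hearts. Ahsp, which binds free alpha globin, rose by 2.6 ± 0.63 and the red cell anion exchanger Slc4a1 by 1.92 ± 0.48. Platelet genes had 0 of 14 past by limma in either count and 3 higher at an unadjusted p below 0.05. Camera called them higher (median 0.31, adjusted p = 0.00187, and adjusted p = 0.59 with an estimated correlation), with an exact permutation p of 0.343.

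Heart muscle genes gave a mixed picture in T5R1. Cardiac stress genes rose in 6 of 18 (7 adjusted over the list alone; adjusted p = 5.46e-07, and adjusted p = 0.0827 with an estimated correlation). The matrix protein Cilp rose by 2.78 ± 0.32, the skeletal actin Acta1, re-expressed in stressed heart muscle, by 1.74 ± 0.28 and the actin-binding Xirp2 by 0.91 ± 0.17. The natriuretic peptide genes did not pass, with Nppa at -0.05 (adjusted p = 0.908) and Nppb at 0.06 (adjusted p = 0.932). Outside the lists, the stress-induced Sprr1a rose by 3.10 ± 0.56. Oxidative phosphorylation genes fell in 16 of 36 (25 adjusted over the list alone), all 36 being measured lower, with a median of -0.26 (adjusted p = 1.77e-08, and adjusted p = 0.275 with an estimated correlation). Examples are the cytochrome c oxidase subunit Cox7a1 (-0.51 ± 0.09) and the complex I subunit Ndufs1 (-0.46 ± 0.08). Fatty acid oxidation genes fell in 10 of 26 (15 adjusted over the list alone), again with all 26 measured lower (adjusted p = 0.000135, and adjusted p = 0.3 with an estimated correlation). Hadha, of the mitochondrial trifunctional protein, was among them (-0.51 ± 0.11). Skeletal muscle markers fell in 5 of 12 (8 lower and 1 higher adjusted over the list alone; adjusted p = 0.00448, and 0.0274 with an estimated correlation). The calcium channel Cacna1s stood at -0.80 ± 0.12 and the slow troponin Tnni1 at -0.63 ± 0.16, the latter with overlapping arms. Atrial markers fell in 3 of 13 (7 adjusted over the list alone; adjusted p = 0.0273, and adjusted p = 0.639 with an estimated correlation). The potassium channel Kcnj3 stood at -0.95 ± 0.15.

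Glucocorticoid receptor targets, the genes switched on by stress hormone, were not called as a list. Of 24 genes 2 rose and 2 fell (2 and 5 adjusted over the list alone; median -0.35, adjusted p = 0.223). The growth inhibitor Ddit4 fell by 1.11 ± 0.25, and Fkbp5, a chaperone of the receptor, stood at -0.33 (adjusted p = 0.375). Heat shock genes fell in 6 of 26 (8 adjusted over the list alone), a list that was not called (adjusted p = 0.0869). The chaperones fell, Hspa1a by 2.51 ± 0.71, Dnajb1 by 1.23 ± 0.40 and Hsph1 by 1.03 ± 0.31. The B cell attractant Cxcl13, outside that list, was lower (-1.998 ± 0.58, overlapping arms, 3 stressed arrays above background). B cell markers had 0 of 12 past by limma in either count and 0 at an unadjusted p below 0.05 (adjusted p = 0.472). T and NK cell markers rose in 1 and fell in 3 of 19 in either count (adjusted p = 0.547). The counts were, for endothelial markers, 2 and 1 of 18 (adjusted p = 0.773), for smooth muscle and pericyte markers 1 and 2 of 15 (2 and 3 adjusted over the list alone; adjusted p = 0.472) and for contractile genes 0 and 2 of 22 (adjusted p = 0.176). Immediate early genes fell in 2 of 23 (adjusted p = 0.773), adipocyte markers in 2 of 16 (median -0.74, adjusted p = 0.177) and adrenergic, calcium handling and channel genes in 3 of 21 (adjusted p = 0.45), with the same counts adjusted over the list alone. Glycolysis genes rose in 1 and fell in 4 of 22 (adjusted p = 0.934), and NRF2 genes in 2 and 4 of 22 (adjusted p = 0.934). Cholesterol genes rose in 2 and fell in 2 of 23 (3 and 2 adjusted over the list alone; adjusted p = 0.0572), circadian clock genes in 1 and 1 of 20 (0 and 1 adjusted over the list alone; adjusted p = 0.154) and MHC class II genes in 1 and 0 of 15 (adjusted p = 0.773). Thymocyte markers (8 genes) and lung markers (7 genes) had 0 past by limma in either count, with 1 higher and 2 lower and with 0 at an unadjusted p below 0.05 (adjusted p = 0.934 for both). The thymocyte, endothelial, smooth muscle, lung, glycolysis and MHC class II lists had negative medians with a camera direction upward.

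In every T5R1 gene named above as changed, the arrays of the arms did not overlap except where stated. Ccr2, Ccl3, S100a8, S100a9, Hsph1 and Cxcl13 lost their call in 4 or 5 and Dnajb1 in 11 of 17 or 18 alternative settings, Cox4i1, Hspa1a and Tnni1 in 2 and Sprr1a, Ahsp, Slc4a1 and Cxcl10 in 1. Under normexp Cthrc1 stood at 2.11, Pbk at 0.84, Ska1 at 0.70, Bub1 at 0.46, Top2a at 0.77, Cdca3 at 1.42, Lox at 0.73, Cd68 at 0.59, Ccr2 at 0.95, Cxcl13 at -1.15 and Tnni1 at -0.37, all past, and Ccl3 at 0.21 and S100a8 at 0.93, which did not pass. The cell cycle median was 0.95 there, and under quantile normalisation Cox7a1 stood at -0.25 and the oxidative phosphorylation median was -0.07. The share of lower calls was 61.4%, but 40.0% under quantile normalisation (1836 higher, 1224 lower) and 38.7% with the authors' values (1852 and 1167). The count was 2177 without stressed replicate 1 and 2412 without control replicate 2, and without stressed replicate 3 the erythroid and platelet lists were not called (adjusted p = 0.0598 and 0.0697).

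After 5 days of exposure and 10 days of rest (T5R10), few single genes passed. The collagen list was called higher as a group, but not with an estimated correlation (adjusted p = 0.999), and 0 of 29 members passed. By limma 21 genes passed, 6 higher and 15 lower, and 3843 had an unadjusted p below 0.05. The largest fall among genes with an official symbol (4 of the 15) was that of Cabp5, a neuronal calcium-binding protein (-1.71 ± 0.24, adjusted p = 0.00129; chromosome 7 from 13993821 to 13993880). The keratin Krt27 (-1.40 ± 0.28), Dcaf12l2 (-1.36 ± 0.28) and the cannabinoid receptor of immune cells Cnr2 (-1.09 ± 0.21, overlapping arms) also fell. The higher genes changed little. The 5 with an official symbol were the DNA repair enzyme Ogg1 (0.42 ± 0.08, adjusted p = 0.0236; chromosome 6 from 113284105 to 113284164), Tceal1 (0.55 ± 0.11), the calpain inhibitor Cast (0.46 ± 0.09), the endosomal sorting protein Vps35 (0.41 ± 0.08) and Pdk1, a kinase that restrains pyruvate oxidation (0.37 ± 0.07).

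In T5R10 collagen and matrix genes were measured higher in 25 of 29, with a median of 0.38 (adjusted p = 2.79e-06, but adjusted p = 0.999 with an estimated correlation). By limma 0 of them passed in either count, and 10 were higher at an unadjusted p below 0.05. The list mean was 0.10 to 0.56 higher in stressed hearts (exact permutation p = 0.0286, not adjusted over 33 lists). Col3a1 stood at 0.90 ± 0.32 (adjusted p = 0.206), Cilp at 1.36 ± 0.32 (adjusted p = 0.0814) and Myh7, the slow myosin heavy chain that mouse hearts make under load, at 1.62 ± 0.39 (adjusted p = 0.0814). Each was higher in all 4 stressed hearts than in any control. Camera also called cardiac stress genes higher (median 0.14, adjusted p = 0.0285), glucocorticoid receptor targets higher (0.18, 0.0285), NRF2 genes higher (0.08, 0.0161) and interferon response genes lower (-0.19, 0.00401). Their adjusted p with an estimated correlation was 0.999, 0.999, 0.885 and 0.999, and their exact permutation p 0.171, 0.229, 0.0571 and 0.229. By limma 0 members of these lists passed over all genes. Adjusted over the list alone 2 cardiac stress genes and 1 glucocorticoid target were higher and 1 interferon gene was lower. The first and second of these calls each ended on leaving out any of 4 single arrays and the others any of 3, with the cardiac stress median at 0.05 without stressed replicate 4 and the interferon median at -0.09 without control replicate 2. At an unadjusted p below 0.05 there were 3, 1, 4 and 2 in the called directions. Values that did not pass include Fkbp5 (0.48, adjusted p = 0.385), the GTPase Mx2 (-0.76, 0.0836) and the sterol synthesis enzyme Cyp51 (0.48, 0.0671). Adipocyte markers were measured higher in 16 of 16 (median 0.46, adjusted p = 0.067), a list whose mean varied with an SD of 0.97 between mice of a group. Cell cycle genes had a median of 0.02 (adjusted p = 0.913), fibroblast markers 0.09 (0.0632), macrophage markers -0.15 (0.0967) and oxidative phosphorylation genes -0.05 (0.195). The lists not named had an adjusted p of at least 0.133.

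Of the T5R10 genes, Cabp5 lost its call in 2 of 19 alternative settings and the others in 7 (Ogg1) to 13 (Vps35). With the T5R10 arrays fitted alone 0 genes passed by limma, though 2551 had an unadjusted p below 0.05, and with replicate blocks 0 as well (4058). The T5R10 count was 5 without control replicate 2, 606 without stressed replicate 2, and 1088 without the 3 arrays that the scanner software marked for evaluation (2 stressed and 3 control arrays left), when Cilp (1.80) and Myh7 (2.33) passed. Lower calls made up 71.4%, against 45.8% under quantile normalisation and 92.9% under normexp, and other splits of the same 8 arrays called up to 1264 genes.

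After 10 days of exposure and 1 day of rest (T10R1), matrix and fibroblast genes were again higher, and the slow myosin Myh7 rose by 2.73 ± 0.39 (adjusted p = 0.000382; chromosome 14 from 55589581 to 55589640). Cilp rose by 2.69 ± 0.32 (adjusted p = 4.4e-05; chromosome 9 from 65128007 to 65128066). In total 312 genes passed, 213 higher and 99 lower, and 69 of the higher and 12 of the lower ones changed at least 2-fold. Immediate early genes and glucocorticoid receptor targets were measured lower, and adipocyte markers lower in every member.

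**Figure D2:**
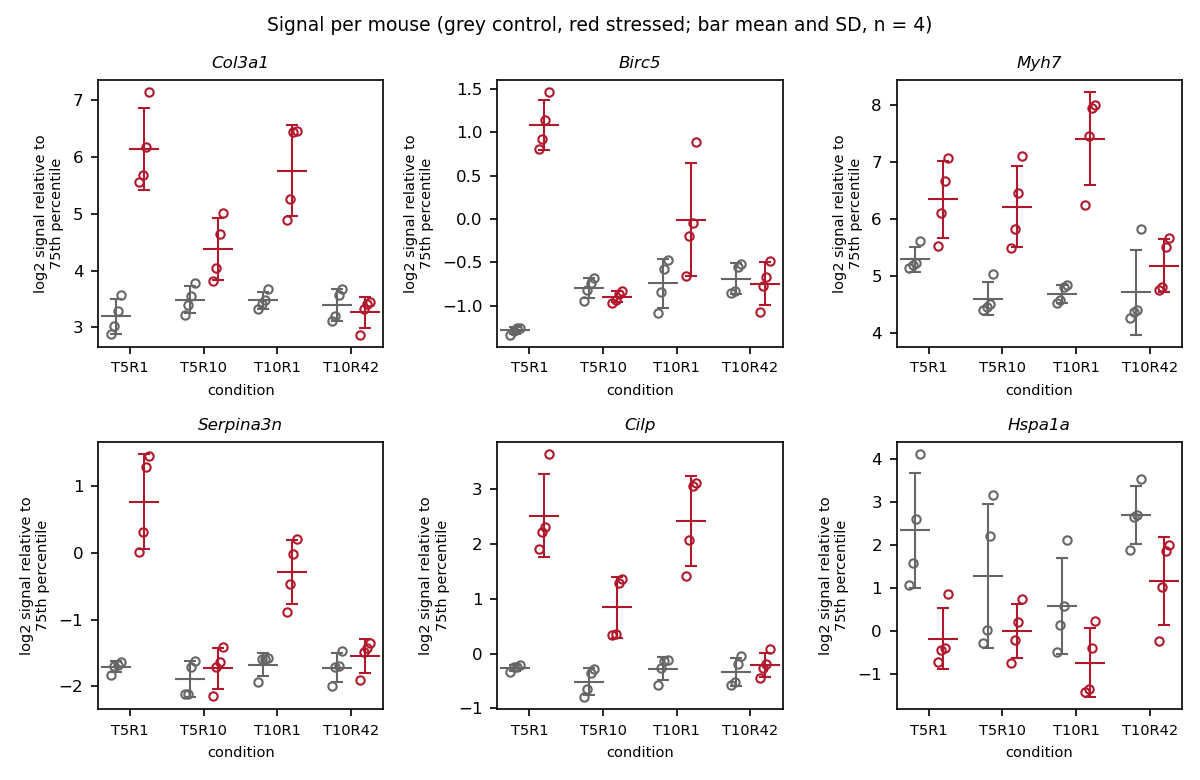
Signal of 6 genes in each mouse, as log2 relative to the 75th percentile of the array (vertical axis), for control (grey) and stressed (red) hearts of each condition, with the mean and SD of 4 mice. Col3a1 was higher by 2.95 in T5R1, 0.90 in T5R10 and 2.29 in T10R1, and Birc5 by 2.37 in T5R1.

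Collagen and matrix genes rose in 19 of 29 in T10R1 (26 adjusted over the list alone), with a median of 1.10 (adjusted p = 3.57e-39, and 0.014 with an estimated correlation). Col3a1 rose by 2.29 ± 0.32, Col1a1 by 2.01 ± 0.30, Postn by 2.05 ± 0.42, Ltbp2, which binds elastic fibres, by 2.11 ± 0.34 and the growth factor Ptn by 2.01 ± 0.34. Cthrc1 was at least 8.43-fold higher, above background on 0 of 4 control arrays. Fibroblast markers rose in 7 of 17 (13 adjusted over the list alone; median 0.56, adjusted p = 3.5e-17, and 0.012 with an estimated correlation). The microfibril protein Mfap4 rose by 1.69 ± 0.22. Matrix remodelling genes rose in 3 of 21 (8 higher and 2 lower adjusted over the list alone; adjusted p = 0.000472, and adjusted p = 0.0785 with an estimated correlation). The gelatinase Mmp2 rose by 1.33 ± 0.20, Adamts2 by 1.19 ± 0.17 and the collagen-degrading protease Ctsk by 1.02 ± 0.18. Cell cycle genes rose in 2 of 31, against 20 higher and 2 lower adjusted over the list alone (median 0.67, adjusted p = 1.04e-10, and adjusted p = 0.166 with an estimated correlation). These were Ccnb2, a cyclin of mitosis (1.11 ± 0.25) and Cdca8, of the chromosomal passenger complex (0.94 ± 0.22), both with overlapping arms. The stressed hearts differed in that list, with means of 1.27, 0.50, 0.35 and -0.05, and without replicate 1 its median was 0.36.

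Macrophage markers rose in 1 and fell in 1 of 20 in T10R1 (7 and 2 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.000189, and adjusted p = 0.245 with an estimated correlation). The growth factor receptor Csf1r rose by 0.45 ± 0.09 and Timd4, of resident macrophages, fell by 0.81 ± 0.20 with overlapping arms. Platelet genes were measured higher in 14 of 14 (median 0.76, adjusted p = 1.65e-07, and adjusted p = 0.21 with an estimated correlation). Of these 1 rose (5 adjusted over the list alone), the adhesion receptor subunit Gp1bb (1.16 ± 0.28). T and NK cell markers had a median of 0.24 (adjusted p = 0.00513, and adjusted p = 0.25 with an estimated correlation) and erythroid markers 0.34 (adjusted p = 0.018, and adjusted p = 0.481 with an estimated correlation). Both had 0 members past by limma in either count, with 4 higher and 1 lower and with 3 higher and 0 lower at an unadjusted p below 0.05. The cardiac stress list rose in 3 of 18 in either count, Acta1 by 1.38 ± 0.28 and Myh7 among them (adjusted p = 0.0035, and adjusted p = 0.261 with an estimated correlation). Serpina3n rose by 1.38 ± 0.25 in the acute inflammation list, which was not called (adjusted p = 0.453), and the apelin receptor Aplnr by 0.85 ± 0.19 in the endothelial list (adjusted p = 0.946).

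Metabolic and hormone-responsive lists were called lower in T10R1, but of these only NRF2 genes also with an estimated correlation. NRF2 genes, which defend against oxidants, fell in 2 of 22 (5 adjusted over the list alone; median -0.19, adjusted p = 3.27e-05, and 0.0351 with an estimated correlation). They were the glutathione transferases Gsta2 (-0.87 ± 0.17) and Gsta1 (-0.81 ± 0.20). Outside that list Cyp1a1, a detoxifying oxidase driven by the aryl hydrocarbon receptor, fell by 1.30 ± 0.29. Immediate early genes were lower in 23 of 23 (median -0.90, or -0.79 with genes at background at their bounds; adjusted p = 2.99e-12, and adjusted p = 0.166 with an estimated correlation). Of these 1 passed (11 adjusted over the list alone), the transcription factor Egr3, at least 1.40-fold lower and above background on 2 of 4 control and 0 of 4 stressed arrays. Glucocorticoid receptor targets had a median of -0.50 (adjusted p = 1.79e-06, and adjusted p = 0.144 with an estimated correlation). By limma 0 passed over all genes, with 1 higher and 10 lower adjusted over the list alone and 1 and 13 at an unadjusted p below 0.05. The clock gene Per1 stood at -0.89 (adjusted p = 0.15) and Fkbp5 at -0.22 (adjusted p = 0.764). Control replicate 3 had an immediate early gene mean of 2.25 against -0.88 to -0.54 in the other controls. Without it the list median was -0.26 and that of glucocorticoid targets -0.37, both still called.

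Adipocyte markers were lower in 16 of 16 in T10R1 (median -1.003, adjusted p = 1.02e-05, and adjusted p = 0.25 with an estimated correlation). By limma 0 passed in either count, 5 were lower at an unadjusted p below 0.05, and the SD between mice of a group was 0.97. Oxidative phosphorylation genes had a median of -0.18 (adjusted p = 7.98e-11, and adjusted p = 0.182 with an estimated correlation) and fatty acid oxidation genes -0.22 (adjusted p = 1.4e-07, and adjusted p = 0.166 with an estimated correlation). In these lists 0 genes passed by limma over all genes, 4 and 2 fell adjusted over the list alone, and 14 and 8 were lower at an unadjusted p below 0.05. Glycolysis genes fell in 1 of 22 (2 adjusted over the list alone; adjusted p = 0.00254, and adjusted p = 0.166 with an estimated correlation), the regulator of glycolysis Pfkfb1 (-0.83 ± 0.18). Contractile genes (median -0.12, adjusted p = 0.00258) and clock genes (-0.18, 0.0185) were called lower, both with adjusted p = 0.25 with an estimated correlation. Heat shock genes (-0.13, adjusted p = 0.0234, and adjusted p = 0.488 with an estimated correlation) and adrenergic, calcium and channel genes (-0.15, adjusted p = 0.0275, and adjusted p = 0.166 with an estimated correlation) were called lower too. By limma 0 members of these 4 lists passed over all genes. Adjusted over the list alone 1 contractile and 2 clock genes fell and 0 in the other two, and at an unadjusted p below 0.05 there were 4, 3, 3 and 3. Clock genes were not called without control replicate 1 (median -0.07) or stressed replicate 3, heat shock genes not without control replicate 3 (-0.05) or stressed replicate 3, and adrenergic, calcium and channel genes not without control replicate 1 (-0.09). Quantile normalisation ended the calls of contractile (median -0.05, adjusted p = 0.201), glycolysis (-0.035, 0.184) and heat shock genes (-0.02, 0.201), as did the authors' values (-0.02, 0.205, -0.05, 0.158, -0.07 and 0.172). Of skeletal muscle markers 2 fell, Cacna1s (-0.48 ± 0.12) and the slow troponin Tnnt1 (-0.39 ± 0.10), in a list that was not called (adjusted p = 0.184), and the lists not named had an adjusted p of at least 0.12.

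Named T10R1 genes had separate arms except where stated, and Cthrc1, Aplnr, Timd4, Gp1bb, Ccnb2, Cdca8, Gsta1, Pfkfb1, Cyp1a1, Egr3, Cacna1s and Tnnt1 lost their call in 5 to 12 of 17 or 18 alternative settings. Under normexp Cthrc1 stood at 1.20, Timd4 at -0.42 and Egr3 at -0.21, none of them past, and Gp1bb at 0.73, with medians of 0.325 for cell cycle and 0.48 for platelet genes. With the T10R1 arrays fitted alone 4 genes passed, with Col3a1, Myh7 and Cilp not among them, and 183 passed under quantile normalisation. Leaving out single arrays gave 86 (stressed replicate 1), 116 (control replicate 2), 123 (control replicate 1), 146 (stressed replicate 4), 176 (control replicate 4) and 185 genes (control replicate 3), and without stressed replicate 1 the erythroid and cardiac stress lists were not called (adjusted p = 0.371 and 0.0506).

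**Figure D3:**
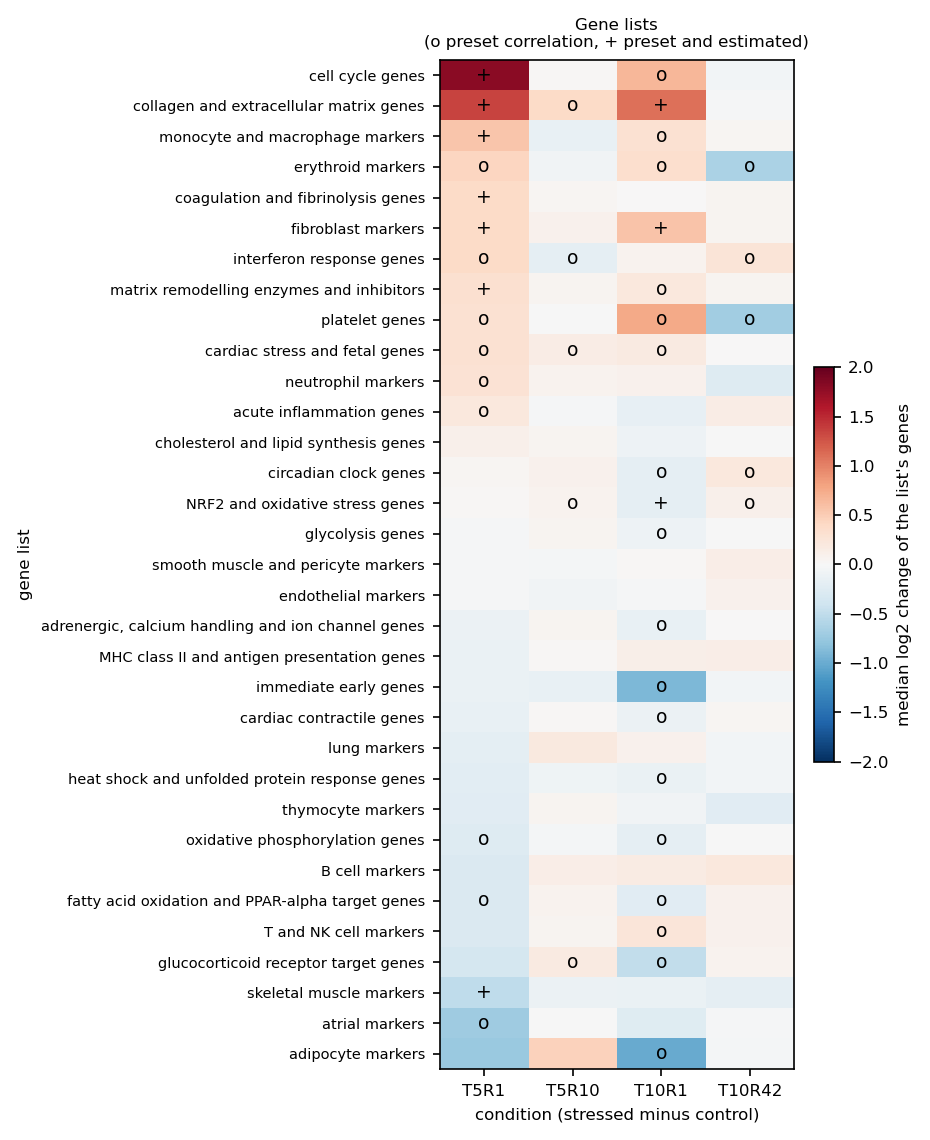
Median log2 change of each gene list (colour) in each condition, with circles for lists called with the preset correlation and plus signs for those called also with the estimated one. Collagen and matrix genes had medians of 1.35 in T5R1, 0.38 in T5R10, 1.10 in T10R1 and -0.03 in T10R42.

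After 10 days of exposure and 42 days of rest (T10R42), a difference in collagen and matrix genes was not detectable (median -0.03, adjusted p = 0.89). By limma 0 of 29 passed in either count and 2 were lower at an unadjusted p below 0.05. Erythroid and platelet lists were called lower and interferon response genes higher, none of them with an estimated correlation (adjusted p = 0.983). In total 247 genes passed, 79 higher and 168 lower, and 6 and 17 of these changed at least 2-fold. With genes split by signal into dim, middle and bright, the lower calls numbered 55, 95 and 18. Klhl15, an adaptor for protein degradation, was at least 1.87-fold higher, above background on 0 of 4 control and 4 of 4 stressed arrays (adjusted p = 0.0122; chromosome X from 91499311 to 91499370), and the odorant receptor Olfr47 fell by 1.03 ± 0.17 with 3 stressed arrays above background (adjusted p = 0.00834; chromosome 6 from 43186188 to 43186247).

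Platelet genes were lower in 14 of 14 in T10R42 (median -0.70, adjusted p = 3.59e-05, and adjusted p = 0.983 with an estimated correlation). By limma 0 passed over all genes, with 7 lower adjusted over the list alone and 10 at an unadjusted p below 0.05. The 4 stressed hearts had list means from -1.12 to -0.51 (exact permutation p = 0.0286), and the platelet glycoprotein Gp5 stood at -0.99 (adjusted p = 0.11). Erythroid markers were lower in 14 of 14 (median -0.63, adjusted p = 0.00727, and adjusted p = 0.983 with an estimated correlation). Here limma called 0 over all genes and 1 adjusted over the list alone, with 3 at an unadjusted p below 0.05, and the red cell carbonic anhydrase Car1 stood at -0.62 (adjusted p = 0.0742). Interferon response genes were measured higher in 28 of 30 (median 0.26, adjusted p = 2.67e-05, and adjusted p = 0.983 with an estimated correlation). Of these limma called 0 over all genes and 1 adjusted over the list alone, with 6 at an unadjusted p below 0.05, and the guanylate-binding Gbp3 stood at 0.71 (adjusted p = 0.0605). Clock genes were higher in 17 of 20 (median 0.22, adjusted p = 0.017, and adjusted p = 0.983 with an estimated correlation). Limma called 0 of them over all genes and 1 adjusted over the list alone, with 3 at an unadjusted p below 0.05. Their median ran from 0.14 without control replicate 4 to 0.37 without control replicate 1, and they were not called in the former case, without stressed replicate 1 or with the authors' values. NRF2 genes had a median of 0.10 (adjusted p = 0.0144, and adjusted p = 0.963 with an estimated correlation), and were not called under quantile normalisation (0.07, adjusted p = 0.239) or with the authors' values (0.06, adjusted p = 0.204). Of these 1 rose (2 adjusted over the list alone), the quinone reductase Nqo1 (0.33 ± 0.08).

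Single genes that rose in T10R42 were the aryl hydrocarbon receptor Ahr (0.58 ± 0.14), the class Ib antigen-presenting H2-M3 (0.55 ± 0.12) and the growth-restraining pocket protein Rbl2 (0.53 ± 0.12). So did the purine synthesis enzyme Adss (0.58 ± 0.11), Scyl3 (0.70 ± 0.13) and the fatty acid dehydrogenase Acadl (0.34 ± 0.08), whose list was not called (adjusted p = 0.0726). The thymidylate synthase Tyms, of the cell cycle list (not called, adjusted p = 0.846), fell by 0.41 ± 0.09. The adhesion molecule Selp, of the acute inflammation list (not called, adjusted p = 0.486), fell by 0.46 ± 0.11. Acoxl (-1.10 ± 0.24, 2 stressed arrays above background), the neuronal calcium sensor Caln1 (-1.06 ± 0.23) and the Wnt receptor Fzd5 (-0.94 ± 0.21, overlapping arms) fell. The small GTPase Rhov was at least 1.32-fold lower, above background on 2 of 4 control and 0 of 4 stressed arrays. Fkbp5 stood at 0.29 (adjusted p = 0.562), endothelial markers had an adjusted p of 0.0732, and the lists not named had one of at least 0.189.

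Among T10R42 genes, Klhl15, Scyl3, Adss and Olfr47 lost their call in 1 to 3 and the others in 6 (Rhov) to 15 (Selp) of 17 or 18 alternative settings. Under normexp Klhl15 (0.175), Scyl3 (0.35), Rhov (-0.27), Acoxl (-0.30), Olfr47 (-0.38) and Fzd5 (-0.42) did not pass. With the T10R42 arrays fitted alone 0 genes passed by limma (5141 had an unadjusted p below 0.05), and quantile normalisation gave 375 genes with 51.2% lower, against 68.0%, and normexp 97 genes. The count was 131, 45, 44 and 86 without control replicates 1 to 4 and 98, 1444, 34 and 53 without stressed replicates 1 to 4.

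The longer rest after 5 days of exposure went with a smaller stress effect on cell cycle genes and, though not with an estimated correlation, on macrophage and interferon genes. The stress effect differed between T5R10 and T5R1 for 686 genes, 326 higher and 360 lower after the longer rest. Cell cycle genes were lower in this difference in 25 of 31 (25 adjusted over the list alone; median -1.72, adjusted p = 3.2e-41, and 0.00905 with an estimated correlation). The DNA repair gene Fanci (-3.08 ± 0.34), the mitotic motor Kif22 (-2.11 ± 0.24), Birc5 (-2.47 ± 0.29) and Cdca3 (-3.15 ± 0.40) had the largest changes among those named, but under normexp Fanci stood at -0.49 and did not pass (adjusted p = 0.11) and Cdca3 stood at -1.43. Collagen and matrix genes were lower in 14 of 29 (23 adjusted over the list alone; -1.06, adjusted p = 3.14e-25, and adjusted p = 0.0629 with an estimated correlation). So were macrophage markers in 7 of 20 (14 adjusted over the list alone; -0.70, adjusted p = 1.1e-12, and adjusted p = 0.0629 with an estimated correlation). Interferon genes were lower in 7 of 30 (21 adjusted over the list alone; -0.59, adjusted p = 3.5e-17, and adjusted p = 0.084 with an estimated correlation). Fatty acid oxidation genes were higher in 2 of 26 (8 adjusted over the list alone; 0.34, adjusted p = 1.67e-06, and adjusted p = 0.185 with an estimated correlation). The muscle M-band gene Myom2 was higher by 0.93 ± 0.14 and the branched-chain amino acid enzyme Ivd by 0.61 ± 0.10. The share of lower genes was 52.5%, 74.4% under quantile normalisation and 72.4% with the authors' values, and the count ran from 311 without T5R1 stressed replicate 1 to 1062 without T5R1 stressed replicate 4.

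The longer rest after 10 days of exposure went with lower stress effects on matrix and platelet genes, though neither list was called with an estimated correlation. The platelet median went from 0.76 in T10R1 to -0.70, below controls, in T10R42. The stress effect differed between T10R42 and T10R1 for 1135 genes, 520 higher and 615 lower after the longer rest. Collagen and matrix genes were lower in 13 of 29 (25 adjusted over the list alone; median -1.07, adjusted p = 9.29e-16, and adjusted p = 0.346 with an estimated correlation). Mfap4 stood at -1.92 ± 0.31, the collagen VI chain Col6a2 at -1.40 ± 0.22 and the matrix protein Ecm1 at -0.94 ± 0.14. Platelet genes were lower in 6 of 14 (13 adjusted over the list alone; -1.59, adjusted p = 2.04e-08, and adjusted p = 0.346 with an estimated correlation). NRF2 genes were higher in 4 of 22 (5 higher and 1 lower adjusted over the list alone; 0.24, adjusted p = 3.63e-05, and adjusted p = 0.0908 with an estimated correlation). The mitochondrial chaperone component Clpx (0.86 ± 0.12) and the membrane-binding Anxa11 (0.61 ± 0.10) were higher. Quantile normalisation gave 566 genes, lower calls were 54.2% against 37.8% under normexp, and the count ran from 305 without T10R42 stressed replicate 3 to 2093 without T10R42 stressed replicate 2.

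Cell cycle genes rose less after longer exposure, though not called with an estimated correlation, and slide and scan day also differed. Between T10R1 and T5R1 163 genes differed, 99 higher and 64 lower after 10 days, and cell cycle genes were lower in 9 of 31 (27 adjusted over the list alone; median -1.16, adjusted p = 1.41e-27, and adjusted p = 0.0644 with an estimated correlation). Fanci (-2.60 ± 0.34), Kif22 (-1.59 ± 0.24) and Cdca3 (-2.46 ± 0.40) were lower, and Cd7, a surface protein of T and NK cells, was higher (1.09 ± 0.18). Under normexp the first 3 stood at -0.36 (adjusted p = 0.222), -1.02 and -0.998 and Cd7 at 0.62 (adjusted p = 0.0598). Interferon genes were measured lower in 29 of 30 (median -0.41, adjusted p = 2.54e-08, and adjusted p = 0.373 with an estimated correlation). By limma 0 of them passed over all genes and 1 adjusted over the list alone, with 1 higher and 8 lower at an unadjusted p below 0.05. Lower calls were 39.3%, against 76.2% under quantile normalisation, 73.4% with the authors' values and 55.0% under normexp, and leaving out single arrays gave 11 (T5R1 control replicate 2) to 321 genes (T10R1 control replicate 1). The count was 12 without a filter on dim probes, 33 with blocks by replicate number, 546 with only the groups compared in the fit and 1991 with array weights.

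**Figure D4:**
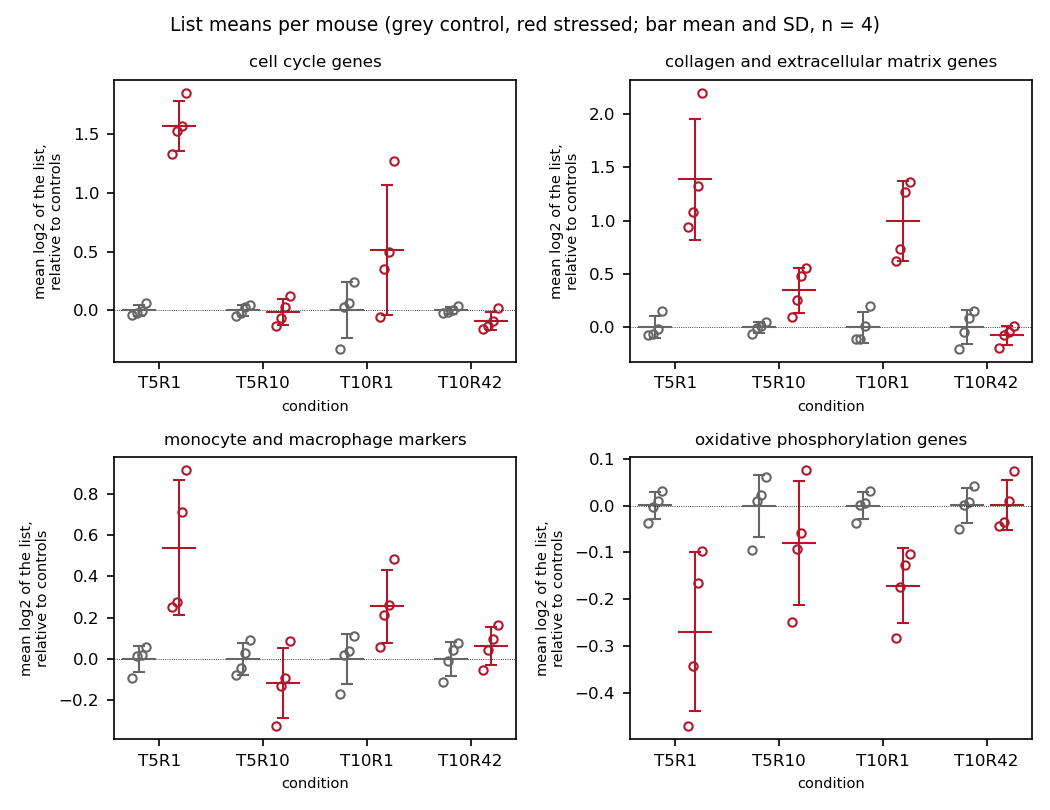
Mean log2 signal of 4 gene lists in each mouse relative to the controls of the condition (vertical axis), for control (grey) and stressed (red) hearts, with the mean and SD of 4 mice. The cell cycle genes of stressed T5R1 hearts lay at 1.33 to 1.85 and those of the controls between -0.04 and 0.06.

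The 2 conditions with 1 day of rest, T5R1 and T10R1, had separate controls. They shared 143 higher (11.3 expected of independent lists, Fisher's exact p = 2.54e-130) and 49 lower genes (8.34 expected, Fisher's exact p = 1.05e-26). T5R1 and T10R42 shared 27 higher (4.18 expected, Fisher's exact p = 1.96e-15) and 65 lower genes (14.2 expected, Fisher's exact p = 3.34e-27). T5R10 and T10R42 shared 2 higher (0.0172 expected) and 0 lower ones, and T10R1 and T10R42 shared 0 in the same direction, with 2 in opposite ones. Genes are not independent and had a single variance for all contrasts, so expected counts and Fisher p are only a guide. Across genes stress effects correlated at 0.33 between T5R1 and T10R1 (by rank 0.14), 0.26 between T5R1 and T10R42 (0.40) and -0.20 between T10R1 and T10R42 (-0.29). So T5R1 was closer to T10R42 than to T10R1 by rank only. Unranked, the bright genes gave 0.51 with T10R1 and 0.18 with T10R42, the dim 0.28 and 0.25. The medians of dim genes lay at -0.22 in both T5R1 and T10R42 and at 0.07 in T10R1. The 143 shared higher genes had in T5R10 a mean 0.26 above controls, with an SD of 0.02 among controls and 0.12 among stressed hearts (exact permutation p = 0.0286, the smallest possible, 0.0572 adjusted over 2 tests), and in T10R42 a mean of -0.004 (exact permutation p = 0.943).

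On average over the 4 conditions 3459 genes passed, 1449 higher and 2010 lower. Collagen and matrix genes rose in 24 of 29 (26 adjusted over the list alone; median 0.70, adjusted p = 5.14e-37, and 0.0122 with an estimated correlation). Cilp rose by 1.74 ± 0.16, Postn by 1.51 ± 0.21 and Thbs4, a matrix glycoprotein of strained tissue, by 1.35 ± 0.15. Fibroblast markers rose in 10 of 17 (14 higher and 1 lower adjusted over the list alone; adjusted p = 3.42e-15, and 0.0122 with an estimated correlation). Matrix remodelling genes rose in 8 of 21 with 1 lower in either count, Timp1 by 1.10 ± 0.16 among them (adjusted p = 5.11e-06, and 0.0122 with an estimated correlation). Cell cycle genes rose in 25 of 31 with 2 lower (27 and 3 adjusted over the list alone; adjusted p = 2.46e-23, and 0.0336 with an estimated correlation). That average came mostly from T5R1, with stressed list means of 1.57 in T5R1, -0.01 in T5R10, 0.52 in T10R1 and -0.09 in T10R42. Skeletal muscle markers fell in 4 of 12 (7 lower and 1 higher adjusted over the list alone; adjusted p = 0.00881, and 0.0352 with an estimated correlation). Immediate early genes fell in 5 of 23 (8 adjusted over the list alone; adjusted p = 0.00458, and adjusted p = 0.767 with an estimated correlation). Atf3, a factor induced by cell stress, stood at -1.39 ± 0.38 and the orphan receptor Nr4a1 at -0.91 ± 0.26. Heat shock genes fell in 7 and rose in 1 of 26 (12 and 1 adjusted over the list alone; adjusted p = 0.0308, and adjusted p = 0.767 with an estimated correlation). Hspa1a fell by 1.66 ± 0.36 and Dnajb1 by 0.76 ± 0.20, and the T cell coreceptor Cd8a fell by 0.92 ± 0.23 (-0.23 under normexp). Oxidative phosphorylation genes fell in 14 of 36 (21 adjusted over the list alone; adjusted p = 2.68e-08, and adjusted p = 0.367 with an estimated correlation), with Ndufs1 at -0.17 ± 0.04. Under quantile normalisation their median was -0.03 and they were not called (adjusted p = 0.0538). Macrophage markers rose in 8 and fell in 1 of 20 (10 and 2 adjusted over the list alone; adjusted p = 1.99e-05, and adjusted p = 0.246 with an estimated correlation) and interferon genes rose in 5 of 30 (8 adjusted over the list alone; adjusted p = 6.73e-06, and adjusted p = 0.559 with an estimated correlation). Cardiac stress genes rose in 7 of 18 in either count (adjusted p = 7.67e-06, and adjusted p = 0.184 with an estimated correlation). Acute inflammation (3 higher in either count), coagulation (3 higher, 5 adjusted over the list alone) and fatty acid oxidation genes (4 lower, 7 adjusted over the list alone) were called at an adjusted p of 0.0352, 0.0211 and 0.0352, or with adjusted p = 0.767, 0.246 and 0.767 with an estimated correlation. The acute inflammation call ended under normexp (median -0.04), with the authors' values and without any of 9 of the 32 arrays, the fatty acid oxidation call under normexp and without any of 12, and the heat shock call under normexp, with replicate blocks and without any of 4. Without T10R1 control replicate 3 the immediate early median was -0.13 instead of -0.32. Myh7 rose by 1.47 ± 0.19 and Serpina3n by 1.05 ± 0.12. The share of lower genes was 58.1%, but 39.1% under quantile normalisation (1855 higher, 1190 lower) and 39.2% with the authors' values (1725 and 1114).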

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

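The tests for thymus tissue and for immature red cells were chosen after the results were seen, as were the block by slide row, the fit without the arrays marked for evaluation, the list tests without single arrays and the column steps of other lists and conditions than cell cycle genes in T5R1.

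The stress effect on cell cycle genes was larger in T5R1 than in T5R10 (adjusted p = 0.00905 with an estimated correlation) and than in T10R1 (not called with it, adjusted p = 0.0644). T10R42 was not tested against T5R1. Between T5R10 and T5R1 686 genes differed: lower after rest were Fanci (-3.08, adjusted p = 3.41e-05), Kif22 (-2.11, 3.41e-05), Birc5 (-2.47, 3.63e-05), Cdca3 (-3.15, 0.000135) and Pidd1, a sensor of surplus centrosomes (-1.68, 0.000135). Higher were those on the calcium-binding Cib3 (2.05, 0.000165), Rdm1 (0.64, 0.000389), Myom2 (0.93, 0.000763), the lactate dehydrogenase Ldhd (0.72, 0.000861) and Ivd (0.61, 0.00189). Between T10R1 and T5R1 163 genes differed, with Fanci (-2.60, 0.00132), Kif22 (-1.59, 0.00586), Cdca3 (-2.46, 0.0116) and the transporters Slc43a2 (-0.83, 0.012) and Slc25a40 (-0.68, 0.0132) lower. Cd7 (1.09, 0.0116), Rdm1 (0.52, 0.0132), Chadl (0.60, 0.028), the helicase Dhx33 (0.47, 0.028) and the potassium channel partner Dpp6 (0.83, 0.0316) were higher. In this difference Dpp6 lost its call in 7, Dhx33 in 5, Chadl in 4, Cd7 and Slc25a40 in 2 and Rdm1 in 1 of 26 alternative settings, and Fanci and Cdca3 in 1 of 25. Under normexp Fanci stood at -0.36 (adjusted p = 0.222) and Cdca3 at -0.998 here, and in T5R10 minus T5R1 at -0.49 (adjusted p = 0.11) and -1.43, with Pidd1 at -0.81. Between T10R42 and T10R1 1135 genes differed, with Ecm1 (-0.94, 0.00223), Siah3 (-0.98, 0.00223), Col6a2 (-1.40, 0.00439) and Mfap4 (-1.92, 0.00439) lower. Clpx (0.86, 0.00201), Ahnak (0.67, 0.00258, with 1 of 3 other probes in that direction), Tmed5 (0.88, 0.00439), Anxa11 (0.61, 0.00468) and the chaperone partner Dnaja2 (0.57, 0.00527) were higher.

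Splits of the same arrays argue against chance for T5R1, where of 35 only the real one gave as many genes (3778 against at most 11). The same holds for T10R1 (1 of 35, 312 against 2) and T10R42 (1 of 35, 247 against 34), though 1 of 35 is the lowest share possible. So it does for the mean (1 of 100 splits, 3459 against 465) and for T10R42 minus T10R1 (1 of 100, 1135 against 14). The share is low for T5R10 minus T5R1 (2 of 100 splits) and T10R1 minus T5R1 (3 of 100) too. Chance is not excluded there, on a stricter view, since other splits called 2383 genes against 686 and 509 against 163. Nor is it for T5R10, since 9 of 35 splits called as many genes as the real 21.

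The rise of cell cycle genes in T5R1 (median 1.80) came with the array columns, since controls and stressed mice lay in different ones. An even gradient across columns is argued against by the step between columns within an arm, a median of 0.10 (SE 0.035 over 31 genes). This holds for these genes only: the step was 0.40 for collagen genes in T5R1 (change 1.35) and 0.22 for cell cycle genes in T10R1 (0.67), where a gradient stays open, but 0.02 for collagen genes in T10R1 (1.10) and -0.24 in T5R10 (0.38). Thymus tissue taken along at dissection is argued against by the thymocyte markers, with a median change of -0.23 (SE 0.125 over 8 genes). An SE over genes takes them as independent, which they are not. Immature red cells in the blood of the heart stay open as a source. Erythroid markers had a median of 0.43 (SE 0.264 over 14 genes). Much of this lay in stressed replicate 3. Without it the erythroid median was 0.21 (adjusted p = 0.0598) and the cell cycle median 1.86. Between stressed hearts the list mean had an SD of 0.68 for erythroid markers and 0.21 for cell cycle genes, a more even rise. Which cells carried the cell cycle RNA stays open, as does an uneven effect of the array column, and division of heart cells under stress is a candidate explanation that was not tested.

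Of the 168 lower calls in T10R42 55 were in dim genes, which were not tested alone. Scaling of the arrays is argued against for most of the 168, since quantile normalisation kept 134, with a median change of -0.59 (median SE 0.132) against -0.63 (0.133). It stays open for the excess of lower calls, whose share fell from 68.0% to 51.2%. Background subtraction stays open too, since normexp on the raw signals kept 63 of the 168, with a median of -0.39 (median SE 0.098). Its offset shrinks the changes of dim genes by construction, so the calls ended with a smaller change rather than a wider error. A lasting effect of stress on these genes was not tested apart from this.

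The T5R10 arrays split more strongly along another line than by stress: of the 35 splits 8 others called more genes than the real 21, the highest with 1264 setting control replicates 1, 2 and 4 and stressed replicate 2 against the other arrays. An exchange of the labels of control replicate 3 and stressed replicate 2 is argued against by the 143 genes higher in both T5R1 and T10R1, over which control replicate 3 lay at -0.011 within the other controls and stressed replicate 2 at 0.145, next to stressed replicate 1 at 0.177. The rows of the slide are argued against, since a split by row called 1 gene. Without the arrays marked for evaluation 1088 genes passed, 330 higher and 758 lower. That leaves 2 stressed and 3 control arrays, of which 4 lie on the side of the split that their arm would take, so these calls may be the split itself or a stress effect. What the split stands for was not tested further, and a biological difference between the mice stays open.

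Single mice stood far from the other mice of their group in 38 of 484 groups tested (25 of 264 list means and 13 of 220 gene values, 7.9% in all), where chance gives about 1 in 20. The measure is the gap to the nearest mouse divided by the range of the 4 mice. T10R1 control replicate 3 did so most often, 5 times, and T5R1 stressed replicate 3 did so 4 times. The former was highest for immediate early genes (0.893), matrix remodelling genes (0.953), cardiac stress genes (0.898) and heat shock genes (0.833) and lowest for Serpina3n (0.941). The latter was highest for Ahsp (0.871) and Slc4a1 (0.835) and lowest for MHC class II (0.834) and NRF2 genes (0.833).

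In T5R1, control replicate 1 was highest for cholesterol genes (0.869) and Fkbp5 (0.904) and lowest for Cxcl10 (0.8294), control replicate 2 highest for MHC class II genes (0.857) and lowest for S100a8 (0.854), and control replicate 3 highest for acute inflammation genes (0.897). Stressed replicate 1 was highest for Fkbp5 (0.831) and lowest for adrenergic, calcium and channel genes (0.832), replicate 2 highest for lung markers (0.902) and replicate 4 lowest for neutrophil markers (0.882). In T5R10, control replicate 1 was lowest for thymocyte markers (0.838), control replicate 2 highest for adipocyte markers (0.92) and lowest for Cast (0.898), and stressed replicate 2 highest for neutrophil markers (0.94) and cholesterol genes (0.87). In T10R1, control replicate 2 was lowest for Adamts2 (0.864), control replicate 4 highest for adipocyte markers (0.837), and stressed replicate 1 lowest for glucocorticoid targets (0.836) and Gsta2 (0.858). Stressed replicate 2 of that condition was highest for platelet (0.852) and glycolysis genes (0.857), and replicate 4 lowest for atrial markers (0.843) and highest for Csf1r (0.947). In T10R42, control replicate 1 was highest for lung markers (0.889), control replicate 2 lowest for thymocyte markers (0.863) and H2-M3 (0.833), stressed replicate 1 highest for Rbl2 (0.866) and stressed replicate 4 lowest for platelet genes (0.915) and skeletal muscle markers (0.93).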

How the results depend on the processing

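Row blocks, fits without marked arrays and list tests without each array were added after seeing the data. Arrays are named by arm and replicate, as control 1. Of 158 gene results 143 passed, and 65 of these passed in every alternative run on them, among them Birc5, Col3a1, Serpina3n and Timp1 in T5R1. Over 3531 alternative values of these genes 3097 kept direction and side of the threshold, 405 no longer passed, 21 newly passed and 8 changed sign. Quantile normalisation kept 129 of 143, normexp 119 of 143, the authors' values 120 of 143, and fits with only the groups of a comparison 63 of 124. The changes of sign were all in genes that passed under no setting: Nppa in T5R1 stood at 0.155 under quantile normalisation, 0.176 with the authors' values, 0.107 with array weights, 0.085 without control 1 and 0.181 without stressed 3, Nppb in T5R1 at -0.021 without control 1 and -0.126 without stressed 1, and Fkbp5 in T10R1 at 0.05 without control 2. Without single arrays Nppa ran from -0.169, Nppb to 0.226 and Fkbp5 from -0.378. The cause was not tested.

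Counts that moved by more than 1.5 times follow, and apart from looser or stricter thresholds and filters the cause was not tested. At an adjusted p of 0.1 the counts were 5721 in T5R1, 170 in T5R10, 563 in T10R1, 1268 in T10R42, 5624 for the mean, and 1454, 2840 and 919 for the differences T5R10 minus T5R1, T10R42 minus T10R1 and T10R1 minus T5R1, as a looser threshold must raise them. Quantile normalisation gave 83 in T5R10, 183 in T10R1, 375 in T10R42, 566 for T10R42 minus T10R1 and 80 for T10R1 minus T5R1. Normexp gave 97 in T10R42. The authors' values gave 33 in T5R10, 127 in T10R42 and 670 for T10R42 minus T10R1. Without a filter the counts were 9 in T5R10, 181 in T10R1, 119 in T10R42, and 392, 451 and 12 for the differences in the order above. With only probes above background on all 32 arrays they were 39 in T5R10, 416 in T10R42 and 308 for T10R1 minus T5R1, and with every probe on its own 9 in T5R10. With only the groups of the comparison in the fit limma called 0 in T5R10 (2551 at an unadjusted p below 0.05), 4 in T10R1, 0 in T10R42 (5141 at an unadjusted p below 0.05), 209 for T5R10 minus T5R1 and 546 for T10R1 minus T5R1, a smaller fit with fewer residual degrees of freedom that does not apply to the mean. Array weights gave 3 in T5R10, 1156 in T10R1, 2220 in T10R42, 4056 for T10R42 minus T10R1 and 1991 for T10R1 minus T5R1. An intensity trend with a robust prior gave 268 for T10R1 minus T5R1. Replicate numbers do not pair the mice (correlations of 16 pairs ran from -0.266 to 0.214, and 6 fitted best with their own number); blocks by them gave 0 in T5R10 (4058 at an unadjusted p below 0.05), 396 for T5R10 minus T5R1 and 33 for T10R1 minus T5R1. Blocks by slide row gave 9 in T5R10 and 296 for T10R1 minus T5R1, and leaving out the arrays marked for evaluation 1088 in T5R10. Blocks by slide and by scan day were not run, since each slide holds 1 condition and the group means absorb both.

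Leaving out single arrays gave 2177 (stressed 1) to 3835 in T5R1, with 2412 without control 2. In T5R10 it gave 5 to 606, with 8, 5, 72 and 7 without control 1 to 4 and 136, 606 and 57 without stressed 1, 2 and 4. In T10R1 it gave 86 to 298, and in T10R42 34 to 1444, with the single arrays in the report. The mean ran from 2589 to 4276. T5R10 minus T5R1 ran from 311 (T5R1 stressed 1) to 1062 (T5R1 stressed 4), with 435, 380 and 403 without T5R1 control 1 to 3, 437 and 354 without T5R10 control 1 and 2 and 370 without T5R10 stressed 3. T10R42 minus T10R1 ran from 305 (T10R42 stressed 3) to 2093 (T10R42 stressed 2), with 433 and 459 without T10R1 control 2 and 4, 338, 703 and 747 without T10R1 stressed 1, 3 and 4, 544, 486, 691 and 538 without T10R42 control 1 to 4 and 686 and 685 without T10R42 stressed 1 and 4. T10R1 minus T5R1 ran from 11 (T5R1 control 2) to 321 (T10R1 control 1), with 34 and 22 without T10R1 control 2 and 4, 319, 16 and 22 without T10R1 stressed 1, 3 and 4, 33 and 49 without T5R1 control 3 and 4 and 34, 21 and 262 without T5R1 stressed 1, 3 and 4.

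Of the tests of lists in the 4 conditions and their mean 60 passed; 15 of them did with an estimated correlation, and fry called 38, 34 of them shared. The direction turned only for acute inflammation genes in the mean, whose median was -0.038 under normexp. Single arrays left out gave 56 to 62 calls, and 762 of 816 values kept their side of the threshold. In T5R1 the atrial list was not called without control 1 (adjusted p = 0.148) or stressed 3 (0.154) and 4 (0.054), or under normexp (0.112) and replicate blocks (0.0702). In T10R1 erythroid markers were not called without control 1 (0.0947). In T5R10 the interferon list was not called without control 2 (0.184) and 3 (0.069) or stressed 1 (0.0669), glucocorticoid targets without control 1 (0.149) and 2 (0.118) or stressed 1 (0.121) and 2 (0.13), and NRF2 genes without control 1 (0.0618) and 2 (0.0882) or stressed 1 (0.0669). Cardiac stress genes lost their T5R10 call without control 1 (0.0765) and 3 (0.129) or stressed 3 (0.0563) and 4 (0.242), and the last 3 lists also under quantile normalisation (0.134, 0.101 and 0.0879) and the authors' values (0.129, 0.0648 and 0.0714), while the collagen list kept its call throughout these. In the mean, acute inflammation genes were not called under normexp (0.125), with the authors' values (0.117) or without any of 9 of the 32 arrays (0.0509 to 0.113). Fatty acid oxidation genes were not called there under normexp (0.335) or without any of 12 arrays (0.0538 to 0.121), nor heat shock genes under normexp (0.229), replicate blocks (0.0534) or without any of 4 arrays (0.0597 to 0.147).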

Other observations

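The list test without T10R1 control replicate 3 was chosen after the data were seen, and the lists described here were picked from the tested ones for not having been described.

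Camera called lists of fuel use and of fat tissue higher after the longer rest, but none of them with an estimated correlation. In the difference T5R10 minus T5R1, adipocyte markers were higher in 16 of 16 with 2 past by limma in either count (median 1.43, adjusted p = 0.00597, and adjusted p = 0.535 with an estimated correlation). In the difference T10R42 minus T10R1 they were again higher in 16 of 16, with 0 past by limma in either count and 4 at an unadjusted p below 0.05 (median 0.99, adjusted p = 0.00137, and adjusted p = 0.502 with an estimated correlation). Their mean varied between mice of a group with an SD of 0.97, against 0.27 for collagen and matrix genes. Oxidative phosphorylation genes were higher in 1 of 36 (4 adjusted over the list alone) after the first rest (median 0.21, adjusted p = 4.56e-05, and adjusted p = 0.414 with an estimated correlation). After the second, fatty acid oxidation genes were higher in 2 of 26 in either count (median 0.28, adjusted p = 1.25e-05, and adjusted p = 0.365 with an estimated correlation). Oxidative phosphorylation genes had 0 past in either count there and 8 at an unadjusted p below 0.05 (median 0.20, adjusted p = 3.63e-05, and adjusted p = 0.468 with an estimated correlation). Glycolysis genes had 1 past in either count there (median 0.09, adjusted p = 0.0181, and adjusted p = 0.398 with an estimated correlation) and were not called after the first rest (adjusted p = 0.438).

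Camera also called glucocorticoid targets higher in both differences with rest and immediate early genes in 1 of them, but not with an estimated correlation. Glucocorticoid receptor targets were measured higher in 21 of 24 in T5R10 minus T5R1, with 2 higher and 1 lower past by limma (5 and 1 adjusted over the list alone; median 0.54, adjusted p = 0.00601, and adjusted p = 0.343 with an estimated correlation). In T10R42 minus T10R1 they were higher in 22 of 24, with 1 past in each direction (1 and 2 adjusted over the list alone; median 0.56, adjusted p = 0.000692, and adjusted p = 0.389 with an estimated correlation). Immediate early genes were higher in 23 of 23 in T10R42 minus T10R1, with 0 past by limma in either count and 6 at an unadjusted p below 0.05 (median 0.82, adjusted p = 1.75e-05, and adjusted p = 0.468 with an estimated correlation). Much of that difference rests on T10R1 control replicate 3, without which the T10R1 median of these genes was -0.26 instead of -0.90, and in T5R10 minus T5R1 their median was -0.04 (adjusted p = 0.741). Erythroid markers were lower in 13 of 14 in T10R42 minus T10R1, with 1 past (4 adjusted over the list alone; median -0.91, adjusted p = 0.000792, and adjusted p = 0.468 with an estimated correlation). Lung markers were high in single hearts of either arm, with means of 1.68 in T5R1 control replicate 4, 1.41 in T5R1 stressed replicate 2, 2.33 in T10R42 control replicate 1 and 2.37 in T10R42 stressed replicate 4 relative to the controls of the condition.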
